A study of Mus musculus with 6 samples.

How the data were processed

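Polyadenylated RNA from the substantia nigra of C57BL/6 mice was sequenced in 6 libraries, 3 from mice fed ad libitum and 3 from mice on intermittent fasting. All mice carried rAAV-A53T-aSynuclein, per the labels. Per the labels' protocols, total RNA was extracted with the RNeasy Lipid Tissue Mini Kit and libraries were made with the NEBNext Ultra II Directional kit, which keeps the strand of each transcript. The authors deposited 1 table of estimated counts per gene, with 19251 genes and 1 column per library, and each value is a whole number that is not scaled between libraries. Per the submitters' processing notes, Salmon and DESeq2 1.40.2 were used with the mouse build GRCm39 (mm39). The notes give neither the role nor the order of these tools. The Salmon version, the annotation release, whether counting used strand and how estimated counts became whole numbers are not given in the sources used here. The smallest sum of any gene over the 6 libraries was 60. Every gene in the table had a name, no symbol occurred more than once, and 0 columns of per-sample values were left unused.

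Libraries were assigned to groups by their labels, and columns to libraries by the names the labels give. Total counts ran from 42990234 to 48179706 per library, so depth differed little between libraries and the spread between samples set the precision. No pair of libraries within a group agreed within counting noise, the smallest chi-square per degree of freedom being 8.19, so all 6 were counted as separate samples. The labels do not say that each library came from a separate animal, so p-values of single genes measure only the spread between these samples.

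The deposited estimated counts were already whole, so rounding changed no value. Genes were filtered with filterByExpr in edgeR 4.0.16 under R 4.3.3, which kept 19109 genes and left 142 untested. Libraries were scaled with TMM factors. Intermittent fasting was compared with ad libitum feeding by the two-sided quasi-likelihood test of edgeR with robust shrinkage of the dispersions, with no covariate, and p-values were adjusted by the Benjamini-Hochberg method. A gene was called at an adjusted p below 0.05. The residual degrees of freedom were 4, the prior degrees of freedom 3.04 and the common biological coefficient of variation 0.171. Log2 fold changes are fasting minus ad libitum throughout. Standard errors were taken as the size of the log2 fold change divided by the square root of the F statistic. Levels are CPM after TMM scaling, computed from the deposited estimated counts, given as mean ± SD over 3 libraries.

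Lists of genes for 38 pathways and cell types were fixed before the data were examined, as were the main test, the rule for named genes and most of the alternatives. Each list was tested against all other genes with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and an inter-gene correlation of 0.01, two-sided, with adjustment over the 38 lists, each of which had at least 5 measured genes. Camera was repeated with a correlation estimated from the data, and fry was run, which tests whether the genes of a list move on balance one way without comparing them with other genes. With the preset correlation, camera p-values rest mainly on the spread between genes, and they do not measure the spread between samples. A permutation of 3 libraries against 3 cannot give an exact p below 0.1. Some genes belong to more than 1 list.

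Named genes were Th, Slc6a3, Gfap, Aif1, Cd68, Sqstm1, Tfeb and Bdnf in any case, and some genes that the rule names are not reported here. To these were added the 10 largest rises and 10 largest falls among called genes whose groups did not overlap and whose mean was at least 1 CPM, and for each list up to 4 called members of smallest p, or up to 2 members of smallest p where none was called. Any other gene named was chosen after its values were seen.

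The reference annotation at hand was GENCODE M21 on GRCm38, another build than that of the files, so no coordinates are given. It was used only to find genes that overlap a called or named gene on the same strand, and the share of that gene's transcript sequence, in words of 31 bases, that also occurs in transcripts of other genes.

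The fits were tested on simulated data with known answers. Counts for the 3 against 3 comparison were drawn from the real means and library sizes. The dispersion of each gene was that estimated by edgeR from the data, the same for both diets. Counts were drawn for 19109 genes, of which edgeR and limma-voom tested the 18937 that passed the filter and DESeq2, run without it, 19105. Of the genes changed, all with a mean count of at least 50, edgeR recovered 43.3% of those changed 1.5-fold, 91.0% of those changed 2-fold and 92.4% of those changed 4-fold, and 7.65% of its calls were false. On the same simulated counts DESeq2 recovered 59.7%, 97.0% and 95.5%, with 25.1% false calls, and limma-voom recovered 35.8%, 91.0% and 92.4%, with 7.98% false calls. Recovery is over the same changed genes for each tool, while the false calls of DESeq2 come from a larger set of tested genes. A list moved in the simulation was recovered at a camera adjusted p of 6.24e-21, or 0.0171 with an estimated correlation, and 0 of 38 unmoved lists were called. Each gene was drawn independently of the others. The simulation therefore cannot show how often camera falsely calls lists whose genes vary together, as real genes can. It also gave both diets the same dispersion, while the real ad libitum libraries differed more from each other than the fasting libraries did. Recovery and false calls may therefore differ in the real data.

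The alternatives tried were DESeq2 1.42.0 and limma-voom in place of edgeR, median-of-ratios and upper-quartile scaling in place of TMM, no low-count filter, a mean count of at least 50, the library number of the labels as a block, each library left out in turn, an adjusted p below 0.1, a change of at least 1.5-fold, and for lists an estimated correlation, fry and at least 10 measured genes. A fit without robust shrinkage, and most settings for the count of list genes, were added after the data had been seen.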

Results

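The study asked how intermittent fasting affects signalling in the midbrain of a mouse model of Parkinson's disease. The labels name the model rAAV-A53T-aSynuclein, where rAAV stands for a recombinant adeno-associated virus, a vector that carries a gene into cells. Mice were allotted to feeding ad libitum or to intermittent fasting 2 weeks after surgery. Fasting lasted 24 hours on each of 3 days a week, and the diet was kept for 10 weeks. RNA-seq was done on the substantia nigra, the midbrain nucleus that holds the dopaminergic neurons lost in the disease, with 3 libraries per diet. The time between the last fast and tissue collection is not given in the sources used here. Total estimated counts were 48106695, 48179706 and 46337950 in ad libitum replicates 1, 2 and 3, and 44392052, 42990234 and 46594066 in fasting replicates 1, 2 and 3.

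The fasting libraries resembled each other more closely than the ad libitum libraries did. Chi-square per degree of freedom between libraries ran from 8.19 to 19.6 within the fasting group and from 42.9 to 77.7 within the ad libitum group. Ad libitum replicate 1 was closer to each fasting library, at 28.8, 30.6 and 31, than to ad libitum replicates 2 and 3, at 77.7 and 45.5. On the first principal component, which held 38.6% of the variance of log2 CPM, the fasting libraries lay between 12.1 and 38.4 and the ad libitum libraries between -47.7 and 0.219. Ad libitum replicate 2 had the highest levels of Chat, a gene of cholinergic neurons, and of Pmch, a gene of hypothalamic neurons. Chat was at 22.9 CPM against 0.656 and 2.14 CPM in the other ad libitum libraries and 0.341, 0.393 and 1.24 CPM under fasting, and Pmch at 432 CPM against 22 and 1.18 CPM and 62.2, 125 and 115 CPM. These genes were chosen after their values were seen.

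Of the genes called in the comparison of all libraries, more were lower than higher in the substantia nigra under intermittent fasting, with microglial, complement and myelin genes among those lower and the glucocorticoid-responsive genes Zbtb16 and Cdkn1a and the RNA-binding protein gene Rbm3 among those higher. Of 19109 genes tested, 95 were called by edgeR, 28 higher and 67 lower under fasting. All 95 were also called by DESeq2. In all 95 the groups did not overlap, which the small p-values of called genes all but ensure. Non-overlap held for 27.5% of all tested genes against 10% by chance, but genes vary together, so this excess is no test. Most changes were modest: 63 called genes differed by at least 1.5-fold and 23 by at least 2-fold, with a median size of 0.73 on the log2 scale. The calls lay close to the threshold, with a smallest adjusted p of 0.0258, and 3890 genes had an unadjusted p below 0.05. The count depended on the tool and on single libraries: DESeq2 called 1395 genes, and edgeR called 1187 without ad libitum replicate 1, 45 without ad libitum replicate 2, 1 without ad libitum replicate 3 and 0 without fasting replicate 1 or fasting replicate 3, where 2452 and 2495 genes had an unadjusted p below 0.05. The share of called genes that were higher was 29.5%, and it was 66.7% without ad libitum replicate 2 and 66.2% without fasting replicate 2, which left 68 calls. Without robust shrinkage edgeR called 9 genes, 7 higher and 2 lower, so the balance of higher and lower calls depended on the setting.

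**Figure D1:**
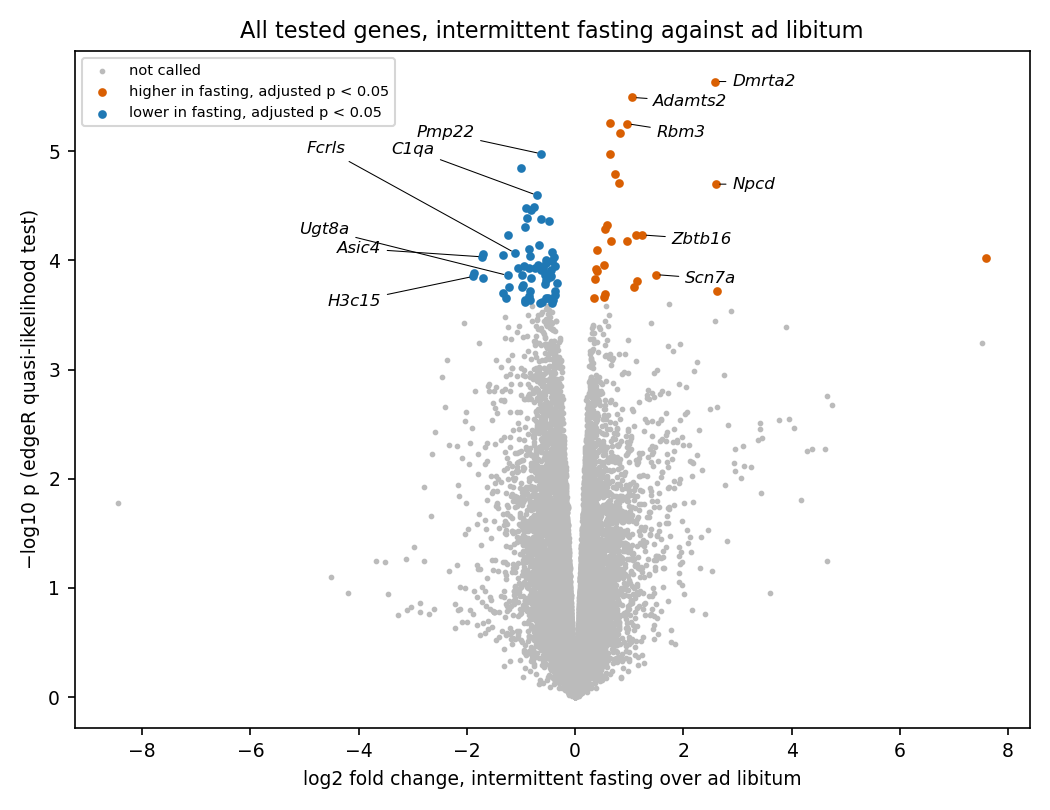
Log2 fold change of intermittent fasting over ad libitum feeding (horizontal axis) against −log10 of the unadjusted p of the edgeR quasi-likelihood test (vertical axis), with each point 1 gene. The 28 called genes that were higher are orange, the 67 that were lower are blue all others are grey and 12 called genes are labelled, while the orange point farthest to the right is Gm47421, whose fitted fold change is no bound because it had 0 counts ad libitum.

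Among the largest rises was Dmrta2 (ENSMUSG00000047143), a transcription factor of the doublesex family, which rose 6.03-fold from 1.18 ± 0.285 to 7.10 ± 0.296 CPM (SD, n = 3), a log2 fold change of 2.59 with an SE of 0.19 (edgeR adjusted p = 0.0258). Npcd (ENSMUSG00000089837) rose by 2.59 on the log2 scale (SE 0.26, edgeR adjusted p = 0.0348), but 96.3% of its transcript sequence also occurs in Cbx6 or Nptxr, which it overlaps, so its value is uncertain. Zbtb16 (ENSMUSG00000066687), a zinc finger transcription factor, rose 2.37-fold to 55.6 ± 6.75 CPM, and Cdkn1a (ENSMUSG00000023067), which encodes the cell cycle inhibitor p21, rose 2.17-fold to 22.9 ± 2.16 CPM. Adamts2 (ENSMUSG00000036545), a protease that trims procollagen, rose from 25.7 ± 2.65 to 53.5 ± 0.786 CPM. Rbm3 (ENSMUSG00000031167), an RNA-binding protein induced by cold, rose 1.95-fold from 65.7 ± 3.19 to 128 ± 11.7 CPM, with a log2 fold change of 0.96 (SE 0.08, edgeR adjusted p = 0.0258). The sodium channel gene Scn7a (log2 fold change 1.49), the phospholipase genes Pla2g4e (1.14) and Pla2g3 (0.97) and Togaram2 (1.10) completed the 10 largest rises. Gm47421 had 0 counts in the 3 ad libitum libraries and 70 in the fasting libraries, which is at least 24.8-fold higher against a floor of 3 counts over the group. All of its annotated sequence occurs in other transcripts, so it is uncertain too, and it lies outside the rule for named genes.

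Among the largest falls was Asic4 (ENSMUSG00000033007), a gene of the acid-sensing ion channel family, which went from 22.9 ± 2.71 to 7.00 ± 1.93 CPM, 3.28-fold lower under fasting, with a log2 fold change of -1.71 (SE 0.20, edgeR adjusted p = 0.0422). The histone genes H3c15 (-1.88), H1f4 (-1.86) and H2bc6 (-1.32) also fell, and 64.2%, 34.7% and 18.2% of their sequence occurs in other genes, so their values are uncertain. Ugt8a (ENSMUSG00000032854), which makes the galactolipids of myelin, fell from 160 ± 17.8 to 67.4 ± 13.6 CPM, 2.37-fold lower. Nkx2-9, a homeobox transcription factor, fell by 1.33 on the log2 scale, and the asparaginase gene Aspg fell by 1.24. Gm10863 (-1.71), 4930506C21Rik (-1.27) and Pagr1a (-1.70) completed the 10 largest falls, and 93.2% of the sequence of Pagr1a is shared with Pagr1b and Gm42742, which overlap it.

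**Figure D2:**
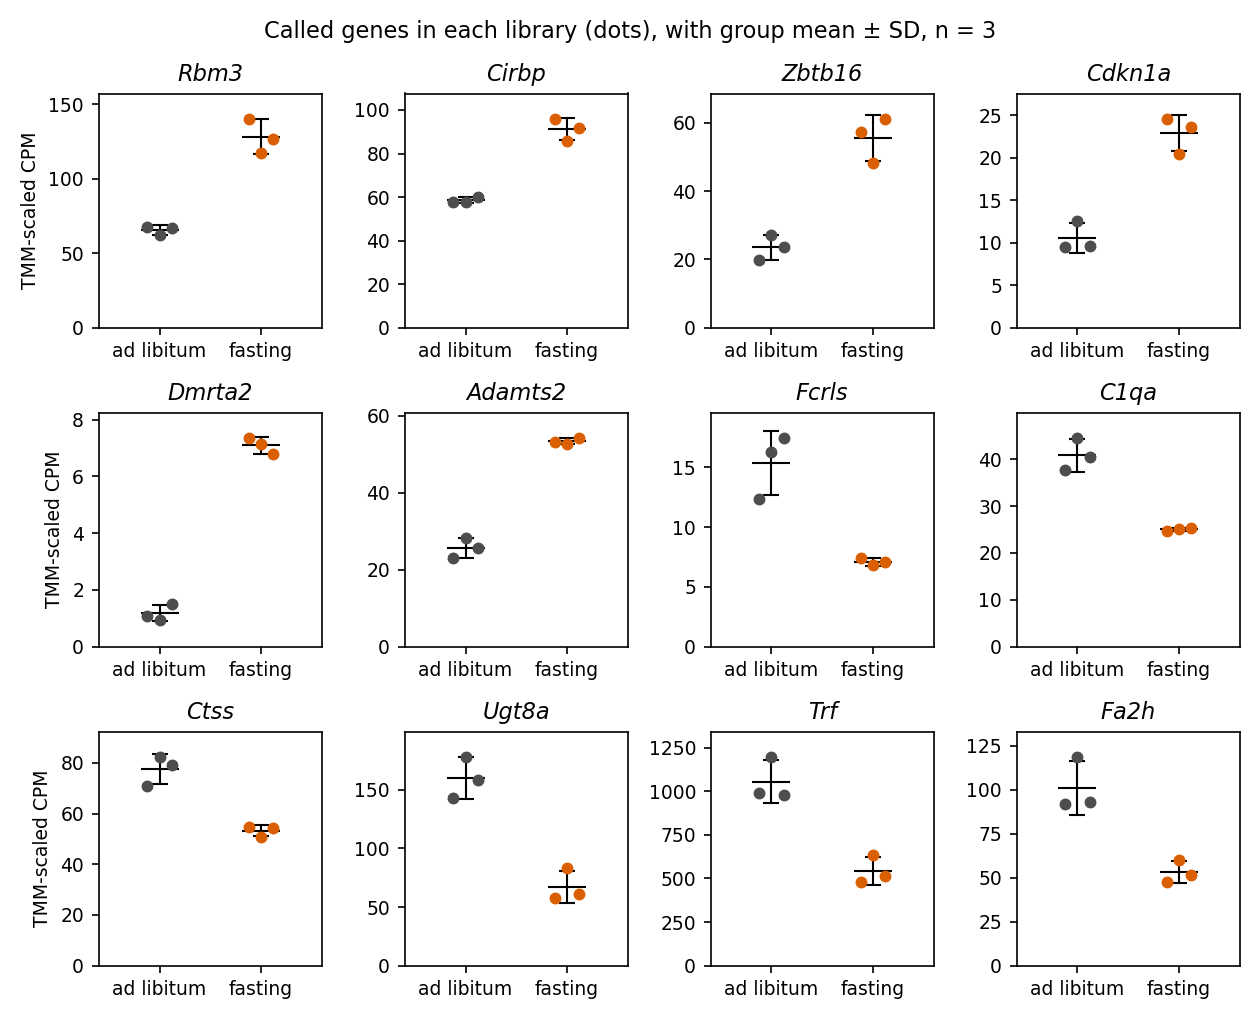
TMM-scaled CPM (vertical axes, each from 0) of 12 called genes in each ad libitum library (grey points) and each fasting library (orange points), with black bars for the group mean ± SD, n = 3. In each panel the points of both diets do not overlap, and Rbm3 lay between 117 and 140 CPM under fasting against 62.0 to 67.8 CPM ad libitum.

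Microglial genes were lower under fasting. Of 15 measured homeostatic microglia markers, all had a negative log2 fold change, with a median of -0.63, but only Fcrls, a microglial receptor gene, passed over all genes. Fcrls fell from 15.4 ± 2.70 to 7.12 ± 0.331 CPM (SD, n = 3), a log2 fold change of -1.11 (SE 0.14, edgeR adjusted p = 0.0422). Adjusted over the list alone, all 15 passed, among them Olfml3 (-1.05), Itgam (-0.73) and Csf1r (-0.60), and Aif1 had a log2 fold change of -0.63 (edgeR adjusted p = 0.0952 over all genes). The list was lower against all other genes (camera adjusted p = 3.13e-10), a call not kept with an estimated correlation (adjusted p = 0.50). Of 20 reactive microglia genes, 0 passed over all genes and 11 adjusted over the list alone, all lower, with a median of -0.50 (camera adjusted p = 2.66e-07, and adjusted p = 0.460 with an estimated correlation). Examples are Ctsz (-0.48), Lyz2 (-0.74, with 32.8% of its sequence shared with Lyz1), Trem2 (-0.58) and Cd68 (-0.50, edgeR adjusted p = 0.103). This was the only list called by fry (adjusted p = 0.0259).

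Complement genes showed the same direction. C1qa and C1qb, which encode chains of the C1q complex made by microglia in the brain, fell from 40.9 ± 3.53 to 25.1 ± 0.323 CPM and from 46.6 ± 4.65 to 27.4 ± 0.907 CPM (edgeR adjusted p = 0.0403 and 0.0422). They were the 2 called of 14 complement genes, 8 passed adjusted over the list alone, all lower, and the list median was -0.55 (camera adjusted p = 1.77e-05, and adjusted p = 0.50 with an estimated correlation). Of 18 antigen presentation genes, 1 fell, the cathepsin gene Ctss (-0.54, SE 0.07, edgeR adjusted p = 0.0422), 2 passed adjusted over the list alone and the median was -0.40 (camera adjusted p = 0.000320, and adjusted p = 0.50 with an estimated correlation). Of 27 interferon-stimulated genes none was called, and 1 passed adjusted over the list alone, Ifitm3 (-0.71, with 20.5% of its sequence shared with other genes). The median of this list was -0.31 (camera adjusted p = 1.25e-06, and adjusted p = 0.50 with an estimated correlation). Of 14 inflammatory cytokine and NF-kB genes 0 were called, 0 adjusted over the list alone, with a median of -0.29 (camera adjusted p = 0.0146, and adjusted p = 0.50 with an estimated correlation), and Tlr2 was at -0.59 and Nfkbia at 0.30. This call ended with DESeq2 (camera adjusted p = 0.0604), with a mean count of at least 50 (0.0684) and without fasting replicate 2 (0.0689). Erythroid genes, which red blood cells carry, moved in the same direction as these groups, with a median of -1.13 over 6 genes (camera adjusted p = 0.0501, not passed, and 0 called). Hbb-bs, the most abundant of them, was at 152, 231 and 646 CPM ad libitum and at 136, 94.6 and 238 CPM under fasting, and 54.4% of its sequence is shared with Hbb-bt.

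Myelin genes were lower under fasting as well. Of 16 oligodendrocyte and myelin genes, all had a negative log2 fold change and 3 fell over all genes: Ugt8a, the iron carrier gene Trf and Fa2h, whose enzyme hydroxylates myelin lipids. Trf went from 1055 ± 124 to 543 ± 82.9 CPM (log2 fold change -0.96, SE 0.13, edgeR adjusted p = 0.0449), with 63.8% of its sequence shared mainly with the overlapping gene Gm20425, and Fa2h went from 101 ± 15.3 to 53.1 ± 6.33 CPM (-0.93, SE 0.13, edgeR adjusted p = 0.0485). Adjusted over the list alone 14 passed, with Mbp at -0.47. The median was -0.58 (camera adjusted p = 1.49e-09, and adjusted p = 0.50 with an estimated correlation). Of 13 genes of oligodendrocyte precursors and immature oligodendrocytes, 0 were called, and 7 passed adjusted over the list alone, among them Sox10 (-0.76), Olig2 (-0.62), Enpp6 (-0.72) and Gpr17 (-0.57). Sox10 and Olig2 are transcription factors of the whole oligodendrocyte lineage, and Pdgfra, the growth factor receptor of precursors, was at -0.03. The median was -0.27 (camera adjusted p = 0.00244, and adjusted p = 0.50 with an estimated correlation).

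Glucocorticoid-responsive genes as a list lay higher under fasting. Of 20 measured, Zbtb16 and Cdkn1a rose over all genes, both among the largest rises, and 18 were not called. Adjusted over the list alone 12 were higher, among them Fkbp5 (0.45), Sgk1 (0.80) and Plin4 (1.82), and 1 was lower, Arrdc3 (-0.29). The median was 0.36 (camera adjusted p = 7.03e-07, and adjusted p = 0.50 with an estimated correlation). Circadian clock genes had a median of 0.14 over 19 genes with 0 called and 0 adjusted over the list alone (camera adjusted p = 0.0263, and adjusted p = 0.568 with an estimated correlation), and Per2 was at 0.34 and Cry1 at 0.35. Of 17 immediate early genes, which neuronal activity induces, 1 fell, Arc, from 28.5 ± 3.33 to 16.1 ± 1.68 CPM (edgeR adjusted p = 0.0422), and 2 passed adjusted over the list alone. The median was -0.23 (camera adjusted p = 0.0470, and adjusted p = 0.50 with an estimated correlation). Relative to the ad libitum mean, the clock and immediate early list means overlapped between diets. Clock genes were at 0.25 in ad libitum replicate 1, and at 0.056 and 0.23 in fasting replicates 2 and 3. Immediate early genes were at -0.17 in ad libitum replicate 3 and at -0.094 in fasting replicate 3. The clock call ended without ad libitum replicate 2 (camera adjusted p = 0.180), ad libitum replicate 3 (0.126) or fasting replicate 1 (0.117). The immediate early call ended without ad libitum replicate 1 (median -0.17, camera adjusted p = 0.0995), ad libitum replicate 2 (median -0.11, camera adjusted p = 0.126) or fasting replicate 2 (median -0.14, camera adjusted p = 0.209), and with a mean count of at least 50 (median -0.24, camera adjusted p = 0.0635). The time from the last fast to collection is not given, so the values of these lists do not separate the last fast from the 10 weeks of diet.

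Chaperone and stress genes lay lower under fasting. Of 16 cytosolic chaperone genes 0 were called and 2 passed adjusted over the list alone, Chordc1 (-0.38) and Cryab (-0.81), with a median of -0.17 (camera adjusted p = 0.00677, and adjusted p = 0.50 with an estimated correlation). Of 23 endoplasmic reticulum and integrated stress response genes 1 fell, the protein disulfide isomerase gene Pdia4 (-0.38, SE 0.05, edgeR adjusted p = 0.0422), and 2 passed adjusted over the list alone, with a median of -0.12 (camera adjusted p = 0.0146, and adjusted p = 0.50 with an estimated correlation). Both calls ended without ad libitum replicate 1, where the chaperone median shrank to -0.094 (camera adjusted p = 0.0696) and the stress response median was -0.14 (camera adjusted p = 0.0940).

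Genes of cholesterol synthesis lay higher under fasting. None of 21 was called and 6 passed adjusted over the list alone, all higher, among them Mvk (0.39) and Lss (0.36), with a median of 0.25 (camera adjusted p = 9.47e-05, and not called with an estimated correlation, adjusted p = 0.50, or by fry, adjusted p = 0.141). Proteasome subunit genes had a small median of 0.10 over 27 genes, 26 of them above 0, with 0 called and 0 adjusted over the list alone (camera adjusted p = 0.000692, and adjusted p = 0.50 with an estimated correlation). Psmd1 was at 0.17 and Psmb7 at 0.13. The 13 mitochondrially encoded genes had a median of -0.07 with 0 called and 0 adjusted over the list alone (camera adjusted p = 0.0276, and adjusted p = 0.50 with an estimated correlation), and mt-Nd2 was at -0.20 and mt-Nd4 at -0.18, with 62.8% of the sequence of mt-Nd4 shared with other genes, so its value is uncertain. This call ended without ad libitum replicate 2 and without fasting replicate 1 or 2, where the highest adjusted p was 0.126. Nuclear-encoded respiratory chain genes did not pass, with a median of -0.02 over 37 genes and 0 called (camera adjusted p = 0.873), nor did 38 cytosolic ribosomal protein genes, with a median of -0.03 (camera adjusted p = 0.653). Fatty acid oxidation, ketone body and PPAR target genes did not pass either (26 genes, median -0.09, camera adjusted p = 0.106). In that list 0 were called and 2 passed adjusted over the list alone, Slc16a1 (-0.39), a carrier of lactate and ketone bodies, and Hadhb (-0.33, with 23.3% of its sequence shared with other genes). Insulin, mTOR and FOXO signalling genes did not pass, with 0 of 26 called, a median of 0.02, a mean of -0.04 and a test direction of up (camera adjusted p = 0.747). Akt2 was at -0.41 and Pik3r1 at -0.27.

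Autophagy and lysosome genes showed no group shift that passed. Of 28 autophagy genes 0 were called and 2 passed adjusted over the list alone, both lower, Wipi1 (-0.52) and Tfeb (-0.41), with a median of 0.06 (camera adjusted p = 0.340). Tfeb, a regulator of lysosome genes, was at 13.9 ± 1.27 and 10.5 ± 0.297 CPM (SE 0.09, edgeR adjusted p = 0.0798), and the autophagy receptor gene Sqstm1 at 375 ± 13.5 and 435 ± 5.86 CPM (log2 fold change 0.21, SE 0.05, edgeR adjusted p = 0.103). Of 30 lysosomal genes 1 fell, Hexa, a subunit of beta-hexosaminidase (-0.43, SE 0.05, edgeR adjusted p = 0.0422). Adjusted over the list alone 2 were higher, Galns (0.44) and Gaa (0.37), and 8 were lower, among them Ctsh (-0.56), Npc1 (-0.40) and Ctsd (-0.20), with a median of -0.04 (camera adjusted p = 0.122).

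**Figure D3:**
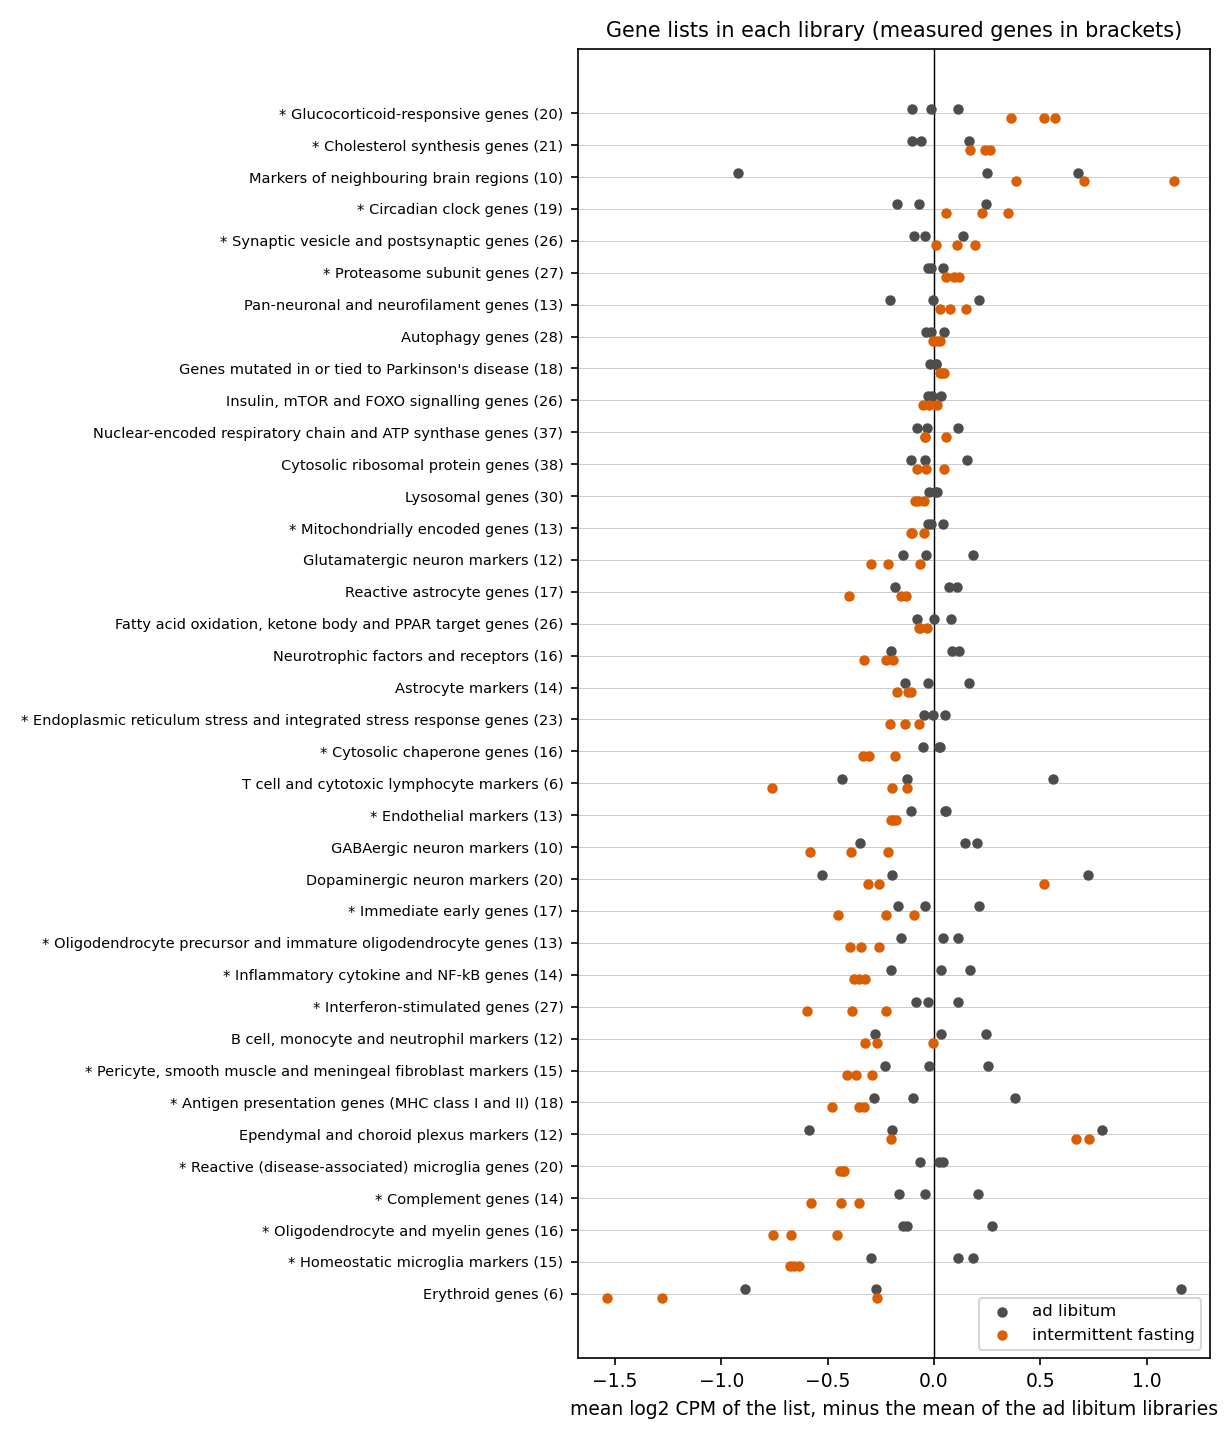
Mean log2 CPM of each of 38 gene lists in each library, minus the mean of the 3 ad libitum libraries (horizontal axis), with 1 row per list, ad libitum libraries in grey and fasting libraries in orange, and an asterisk for the 19 lists called by camera. The fasting libraries lay at -0.63, -0.68 and -0.66 for homeostatic microglia markers, below the ad libitum values of -0.30, 0.18 and 0.11.

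Dopaminergic neuron markers did not differ between diets beyond the spread between libraries. Th, which encodes the rate-limiting enzyme of dopamine synthesis, was at 138 ± 84.8 CPM ad libitum and 129 ± 52.4 CPM under fasting (SD, n = 3), a log2 fold change of -0.10 with an SE of 0.51 (edgeR adjusted p = 0.933). The dopamine transporter gene Slc6a3 was at 380 ± 237 and 268 ± 118 CPM (log2 fold change -0.50, SE 0.53, edgeR adjusted p = 0.641). The 20 dopaminergic markers had a median of -0.21 with 0 called (camera adjusted p = 0.888). The list mean was highest in ad libitum replicate 3, 0.73 above the ad libitum mean, and without that library the median was 0.33 and the list passed as higher (camera adjusted p = 0.0339). The Parkinson's disease gene list had a median of 0.03 over 18 genes with 0 called (camera adjusted p = 0.294), with Fbxo7 at -0.27.

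Of the other neuronal lists, the synaptic genes alone were called. Synaptic genes had a median of 0.13 over 26 genes with 0 called and 0 adjusted over the list alone (camera adjusted p = 0.0216, and adjusted p = 0.50 with an estimated correlation), with Syngr1 at 0.22 and Syp at 0.26. Relative to the ad libitum mean, the synaptic list means of the diets overlapped. Ad libitum replicate 1 was at 0.13, and fasting replicates 2 and 3 were at 0.011 and 0.11. The synaptic call ended without ad libitum replicate 2 or 3 or fasting replicate 1, where the highest adjusted p was 0.107. Pan-neuronal genes had a median of 0.09 over 13 genes (camera adjusted p = 0.148), GABAergic markers of -0.18 over 10 (camera adjusted p = 0.128) and glutamatergic markers of -0.09 over 12 (camera adjusted p = 0.653), each with 0 called. Among their members of smallest p, Uchl1 was at 0.36, Slc32a1 at -0.34 and Lhx2 at -1.07. Markers of neighbouring brain regions had a median of 0.21 over 10 genes (camera adjusted p = 0.340), and their list mean spanned -0.92 to 0.67 within the ad libitum group. Neurotrophic factors and receptors had a median of -0.11 over 16 genes with 0 called (camera adjusted p = 0.340), 1 passed adjusted over the list alone, Hgf (-2.05), and Bdnf was at 13.2 ± 3.03 and 17.0 ± 3.27 CPM (log2 fold change 0.36, edgeR adjusted p = 0.367).

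Astrocyte lists did not pass. The 14 astrocyte markers had a median of -0.12 with 0 called (camera adjusted p = 0.181), and 3 passed adjusted over the list alone, the water channel gene Aqp4 (-1.01) and S100b (-0.44) lower and Fgfr3 (0.27) higher. The 17 reactive astrocyte genes had a median of -0.09 with 0 called (camera adjusted p = 0.102). Gfap, the intermediate filament of reactive astrocytes, was at 480 ± 234 CPM ad libitum and 168 ± 27.3 CPM under fasting, 2.86-fold lower, but did not pass (log2 fold change -1.51, SE 0.41, edgeR adjusted p = 0.138). Of 13 endothelial markers 0 were called, while 6 were lower and 2 higher adjusted over the list alone, with Tek at -0.55, Kdr at -0.49 and the transporter gene Slc2a1 at 0.24. Their median was -0.17 (camera adjusted p = 0.0160, and adjusted p = 0.50 with an estimated correlation), and the call ended without ad libitum replicate 1 or 2, where the highest adjusted p was 0.0858. The 15 pericyte, smooth muscle and meningeal fibroblast markers had a median of -0.37 with 0 called and 0 adjusted over the list alone (camera adjusted p = 0.0146, and adjusted p = 0.50 with an estimated correlation), with Rgs5 at -0.38 and Slc47a1 at -2.66. Without ad libitum replicate 3 this list was still called, but its median shrank to -0.16. Slc47a1 was at 1.95, 3.49 and 14.7 CPM ad libitum against a mean of 1.06 CPM under fasting, so ad libitum replicate 3 carried much of its size. Ependymal and choroid plexus markers went both ways, with a median of -0.44, a mean of 0.40 and a test direction of up over 12 genes (camera adjusted p = 0.886). Among them Tmem212 (4.75) and Ccdc153 (4.28) were higher adjusted over the list alone and Enpp2 (-0.69) was lower. Both rises start near 0, from 0.0214 to 0.103 CPM and from 0.0641 to 0.413 CPM, and fasting replicate 2 was the lowest fasting library, at 0.324 CPM against 2.16 and 2.24 CPM and at 0.855 CPM against 4.68 and 6.78 CPM, so their size is uncertain. B cell, monocyte and neutrophil markers had a median of -0.33 over 12 genes (camera adjusted p = 0.315), and T cell markers a median of -0.17 over 6 (camera adjusted p = 0.752), with 0 called in each.

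In all, camera called 19 of the 38 lists, 5 higher and 14 lower, and 12 of the 691 genes on lists were called over all genes, 2 higher and 10 lower. With an estimated correlation 0 lists were called, and fry called 1. With 3 libraries against 3, the exact permutation p of a list mean could not go below 0.1. The count of list genes moved with tool and library as the count of all genes did, to 117 with DESeq2, 93 without ad libitum replicate 1 and 0 without ad libitum replicate 3, fasting replicate 1 or fasting replicate 3. It was 7 without ad libitum replicate 2 and 5 without fasting replicate 2.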

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

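The fit without robust shrinkage, and the settings for the count of list genes other than DESeq2 and the replicate block, were chosen after the data had been seen. The number of calls and the balance of higher and lower calls were not stable. The count of 95 became 78 with limma-voom, 84 and 92 with the other scalings, 81 without a filter and 82 with a mean count of at least 50. It was 1395 with DESeq2, of which 546 were higher, 963 at an adjusted p below 0.1, 63 with a change of at least 1.5-fold, and 9 with edgeR without robust shrinkage, 7 higher and 2 lower. With 1 library left out it ran from 0 to 1187. Of the 95, DESeq2 called all, edgeR called 25 without ad libitum replicate 2 and 29 without fasting replicate 2, and in those 2 settings 45 and 68 genes were called. Leaving out a library leaves fewer samples, which lowers power, but 1187 calls without ad libitum replicate 1 go the other way, and the cause was not tested. The 12 called genes on lists became 117 with DESeq2, 0 without robust shrinkage and 0 to 93 with 1 library left out.

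The count of 19 lists stayed between 14 and 22 with 1 library left out. It stayed between 17 and 20 with another tool, scaling or filter, the replicate block or lists of at least 10 genes. It fell to 0 with an estimated correlation and to 1 with fry. The camera runs differed in whether the inter-gene correlation was preset or estimated, so the fall to 0 came from that choice. It need not mean that the genes of these lists vary together. In the simulation, where genes were drawn independently, the adjusted p of the moved list also rose, from 6.24e-21 to 0.0171. With the preset correlation camera also called up to 17 lists in splits that mix the diets, so its p-values may be too small. The cause of the fall with fry was not tested. In 13 settings that kept the preset correlation, 11 lists were called each time: both microglia lists, myelin, oligodendrocyte precursors, complement, antigen presentation, interferon, mural and fibroblast markers, glucocorticoid response, cholesterol synthesis and proteasome. The size of some moved more: over these settings the median ran from -0.37 to -0.16 for mural and fibroblast markers, from -0.47 to -0.22 for antigen presentation, from -0.51 to -0.27 for interferon-stimulated genes and from 0.15 to 0.35 for cholesterol synthesis. Among lists that lost their call in some settings it ran from -0.33 to -0.11 for immediate early genes, from -0.22 to -0.094 for chaperones, from -0.34 to -0.18 for inflammatory genes, from 0.078 to 0.17 for synaptic genes, from 0.11 to 0.21 for clock genes and from -0.25 to -0.14 for endothelial markers.

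Whether the library numbers of the labels pair the samples is not known. The correlations of deviations between samples of the same number were 0.21, -0.04 and -0.11. Replicate 1 of each diet correlated best with its own number, and replicates 2 and 3 did not. With 3 samples per group these values cannot decide it. With the replicate block edgeR called 285 genes, 81 of the 95 among them, and 32 genes on lists. The block also ended the list calls of immediate early genes (camera adjusted p = 0.122) and mitochondrially encoded genes (0.0541).

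Signs changed 17 times among 11 reported results, none of them called in the comparison of all 6 libraries. At a mean count of at least 50 the median was 0.093 for glutamatergic markers, which were at 0.053 with limma-voom, and 0.061 for ependymal markers. Th was at 0.0058 with the replicate block. With 1 library left out the dopaminergic median ran from -0.51 to 0.33, the latter without ad libitum replicate 3, where the list was called. The ependymal median ran from -0.72 to 0.027, insulin signalling from -0.012 to 0.045, neighbouring regions from -0.17 to 0.28, nuclear respiratory chain genes from -0.068 to 0.025, ribosomal protein genes from -0.086 to 0.051 and T cell markers from -0.40 to 0.19. Th ran from -0.48 to 0.53, Slc6a3 from -0.92 to 0.14 and Cd4 from -4.72 to 0.50. The cause was not tested. Depth was alike in all libraries, so the spread between samples sets the limit. In the simulated comparison, which gave both diets the same dispersion, edgeR recovered 43.3% of 1.5-fold changes.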

Other observations

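The tests of a lower share of microglia or oligodendrocytes, of fewer glia and of colder tissue were chosen after the values had been seen, as were the genes named here outside the rule.

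Some called genes on no list are given here singly, and no group of them was tested. Cirbp, like Rbm3 an RNA-binding protein induced by cold, rose from 58.6 ± 1.43 to 91.2 ± 5.11 CPM (SD, n = 3), a log2 fold change of 0.64 with an SE of 0.06 (edgeR adjusted p = 0.0292). Mfsd2a, which carries lipids with omega-3 fatty acids, rose by 0.84 on the log2 scale, and Slc7a5, which carries large amino acids, by 0.38. Etnppl, an enzyme of phosphoethanolamine breakdown found in astrocytes, rose from 94.0 ± 1.41 to 156 ± 13.1 CPM. Genes that fell include Pmp22 (-0.63), Plxnb3 (-0.92), the gap junction gene Gjb1 (-0.86), the RNA-binding protein gene Qki (-0.55), Lcp1 (-0.53), Mpeg1 (-0.59) and Bin2 (-0.99). The chemokine gene Cxcl12 fell by 0.67 and the nuclear RNA Neat1 went from 325 ± 18.7 to 194 ± 23.4 CPM (edgeR adjusted p = 0.0422).

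Genes of hypothalamic neurons varied in level between libraries. Hcrt and Pmch ranked the 6 libraries alike, with ad libitum replicate 2 highest, while Npvf and Oxt did not follow them. Hcrt, the orexin gene of the lateral hypothalamus, was at 71.5 CPM in ad libitum replicate 2, at 0.995 and 0.0641 CPM in replicates 1 and 3, and at 2.71, 17.2 and 9.28 CPM under fasting. Npvf, also hypothalamic, was at 4.48, 1.30 and 7.19 CPM in the fasting libraries and at 0 to 0.0620 CPM ad libitum (edgeR adjusted p = 0.0599, not called), with no overlap between groups. Like Tmem212 and Ccdc153, Npvf was near 0 in every ad libitum library and, under fasting, lowest in replicate 2. Oxt, with 21.3% of its sequence shared mainly with Avp, was at 33.4, 0.162 and 2.90 CPM under fasting and at 0.339, 2.44 and 0.192 CPM ad libitum.

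The 3 against 3 design gives 10 splits of the libraries, too few for a share under 0.05. The real split gave 95 genes and the highest other split 0, and the real split gave 19 lists and the highest other split 17. Of the 19 called lists, 11 had another split with an adjusted p as small, among them cholesterol synthesis, where 2 other splits did and the lowest was 6.25e-12, and 8 had none, among them both microglia lists, complement, myelin and glucocorticoid response.

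The lower microglial genes may reflect fewer microglia or lower expression per cell. More blood in the ad libitum tissue is argued against, though weakly, by a fit with the mean of 6 erythroid genes, 0 of them on another list, as a covariate. The homeostatic microglia median then moved from -0.63 to -0.49 (SD over members 0.151, camera adjusted p = 1.77e-08, and adjusted p = 0.60 with an estimated correlation). The erythroid median moved from -1.13 to 0.00, but the covariate is made of the same genes, so that move was fixed in advance. For dissection of different regions, a component of the neuron and region genes, which held 54.5% of the variance of 52 genes, served as a covariate. With it the median was -0.63 (SD 0.164, camera adjusted p = 4.58e-09, and adjusted p = 0.558 with an estimated correlation). The component was at -0.62, 1.28 and -1.58 ad libitum and at 0.47, -0.057 and 0.51 under fasting. The fasting libraries thus lay within the ad libitum range, so this covariate could hardly move the median. Npvf and the ependymal markers Tmem212 and Ccdc153, which lay higher under fasting, were not among its genes, so dissection stays open. With an estimated correlation the list was not called without a covariate either (adjusted p = 0.50), so the argument against blood rests on the size of the median. The spread of that median over libraries was not computed, so the argument is weak. The blood covariate took up part of the fall, so only blood as the whole cause is argued against. A lower share of microglia alone would lower all 15 markers alike only if microglia alone, and all of them equally, expressed each marker. The departure of 2 of the 15, Fcrls and Olfml3, from the list mean argues only against that simple case, which was not tested further. For the other 13 genes, which lay between -0.73 and -0.52, 0 departed, but this decides nothing, since the genes that departed had been left out. A lower share cannot be told apart from lower expression, because no cell counts were analysed here, and an effect of the diet itself is open.

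The lower myelin genes, too, were weighed against dissection and cell share. With the region component as a covariate the myelin median was -0.66 (SD over members 0.230, camera adjusted p = 6.77e-11, and adjusted p = 0.558 with an estimated correlation, or 0.50 without the covariate). As that component hardly separated the diets, this does not argue against different regions, which stay open. If mature oligodendrocytes alone, and all of them equally, expressed these 16 genes, a lower share alone would lower all 16 alike. Yet 10 of 16 departed from the list mean, with Ugt8a at -0.63 and Cldn11 at 0.31 relative to it. That mean is itself drawn down by Ugt8a, Trf and Fa2h, which fell most. The departures argue only against that simple case, since expression in other cells or in part of the oligodendrocytes was not tested. A partial loss of cells was not tested, and an effect of the diet stays open.

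The higher Rbm3 and Cirbp may go with a lower body temperature during fasting, which was not measured in these data. Fewer glia raising every other transcript is argued against, since the median of the 13 pan-neuronal genes was 0.086 against log2 rises of 0.96 and 0.64. Colder tissue was assumed also to lower targets of heat shock factor, which these data cannot test. The median of these targets was -0.086 over 13 genes, with 11 below 0 (camera p = 0.0242, and p = 0.366 with an estimated correlation). That leaves colder tissue open, since it cannot be told apart from other effects of the diet with these libraries.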
